A study of Mus musculus with 4 samples.

How the data were processed

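The series profiled Pcbp1, a poly-C-binding protein known to bind RNA and DNA, by chromatin immunoprecipitation sequencing (ChIP-seq) in E14 Tg2a mouse embryonic stem cells. Per the labels, naive cells were adapted for 3 passages to serum-free medium with LIF and inhibitors of MEK and GSK3. Primed epiblast-like cells (EpiLC) were derived from them with bFGF and Activin A for 48 hours. Each condition had 1 Pcbp1 ChIP library and 1 input library, which makes 4 groups of 1 library. The labels place chromatin fragments at around 500 bp.

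The authors deposited 1 peak list per condition, each called on a single ChIP library, so nothing was pooled over replicates. The submitters' processing notes name fastp, Bowtie2, Picard and MACS2 and the mouse build GRCm38 (mm10), with no versions, roles or order. Which control the caller used is not given in the sources used here. The deposited fold enrichment is a ratio over the caller's background at the summit, as the authors' caller wrote it. The deposited −log10 p-value and −log10 q-value are the authors' values for each peak, and the lowest −log10 q was 2.02 in both lists, which places the threshold at a q of 0.01. The other deposited column used gives the distance of the summit from the peak start.

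Read totals are not given in the sources used here. Depth was therefore described from the peaks themselves. The fold was read as (pileup + 1) / (background + 1) and the p-value as the Poisson probability of a larger pileup, and both were solved for the pileup and the background. A whole-number pileup gave the deposited −log10 p within 0.001 for 100% of the 12132 Naive and 3494 EpiLC peaks, with a single matching pileup for each. The lowest background in a list was taken as its genome-wide background, and the local background of a peak was expressed relative to it. From the pileup, a 95% Poisson interval was given for each fold. These intervals, and the exact binomial intervals given for shares, cover counting error only and hold no variation between cultures or libraries. The recovery returned 100% of 3000 simulated pileups, and planted overlaps were classed correctly in 100% of 1000 simulated peaks. The simulations used the formulas and the overlap rule assumed here. They check the code, not the reading of the deposited values.

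Peaks were compared by an overlap of at least 1 bp with bedtools 2.31.1 and with Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, scipy 1.17.1), which returned the same numbers. Random expectations came from 100 placements of the peaks on their own chromosomes. Where several peaks overlapped 1 peak, the one with the highest fold was used. Figures were drawn with matplotlib 3.10.9.

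Genes were taken from a RefSeq table of GRCm38.p6, the build of the peak lists, with 21887 protein-coding genes on the placed chromosomes. The table holds gene starts and ends without strand, transcripts or sequence. The planned promoter was therefore replaced by a gene end: a gene had a gene-end peak when a summit lay within 1 kb of either annotated end. Such a peak can lie at the 3' end of a gene. The planned search for C-rich sequence at summits, the transcript-start window and the random lists matched on GC content needed strand or sequence and were not run.

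Before the data were examined, 26 gene lists were fixed: naive, core and primed pluripotency, 2-cell-like genes, other lineages and fibroblasts, amino acid synthesis, degradation, transport and sensing, the integrated stress response, iron handling, splicing, translation, glycolysis, respiration, histones, and 2 control lists. All their members were matched to the table, 1 of them by an older symbol. Each list was tested in each peak list with a two-sided Fisher's exact test against all other protein-coding genes, with Benjamini-Hochberg adjustment over the 52 tests and a threshold of 0.05. In 100 simulated rounds, 5 lists planted at an odds ratio of 6 were called in 96.2% of cases at the Naive rate of peaks and in 74.2% at the EpiLC rate, and other lists were called in 0.500% of cases. These tests describe which genes a peak list holds and compare neither libraries nor conditions. With 1 library per condition no test between conditions was possible, and no p-value is given for one.

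A second set of 26 Fisher's exact tests took the genes with a gene-end peak in 1 peak list only and asked whether a gene list split between the peak lists like other genes did. Their p-values compare the peak lists with genes as units. They hold no variation between cultures or libraries and are no test between conditions. Peaks within 50 kb of a gene body were also counted and set beside 10000 random gene lists matched on gene length. A peak near several genes of a list was counted once, while in the random lists it was counted at each gene, which can only lower the ratios. The split tests and these counts were chosen after seeing the data, as were the comparison of pileups in place of folds and the windows with many EpiLC-only peaks.

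The genes named were set by a rule fixed before the data were examined: 11 genes whatever their value, the 8 genes with the strongest gene-end peaks in both peak lists (by the lower fold), the 8 strongest in each list alone, up to 4 members of each gene list, and the 5 peaks of highest fold in each list. Other genes are marked as chosen after their values were seen. Some genes that would have been named are not reported here. Alternatives covered the peak threshold, the overlap that counts as shared, equal list lengths, the gene-end window, the chromosomes used and the merging of nearby peaks. Input libraries entered only through the authors' peak calling and were not analysed here.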

Results

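Pcbp1 ChIP-seq was compared between naive mouse embryonic stem cells and primed EpiLC, the state that follows naive pluripotency in culture. The series is concerned with the part Pcbp1 plays in this transition and in amino acid metabolism. The Naive list held 12132 peaks with a median fold enrichment of 4.43 (quartiles 3.80 and 5.41). The EpiLC list held 3494 peaks with a median of 3.41 (quartiles 2.87 and 4.15). Median peak widths were 362 and 308 bp. The EpiLC calls rested on the deeper coverage: the genome-wide background was 7.43 in EpiLC and 4.004 in Naive, a ratio of 1.86, and the median summit pileup was 45 against 24. Each condition had 1 ChIP library, so the values below carry no replicate error, and a peak missing from a list is not evidence that Pcbp1 was absent there.

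Ranked by the lower fold, the strongest gene-end peaks found in both lists were those of Snx12, Hexim1, Tob2, Dera, Usp9x, Zfp143, Mkx and Kmt2a. Shared peaks away from gene ends were not ranked in this way. The peak at Snx12, a sorting nexin gene (chromosome X, 101222314 to 101222940 in Naive), had a fold of 44.96 (95% counting interval 39.3 to 51.2) in Naive and 26.7 (23.8 to 29.9) in EpiLC. Mkx reached 34.2 in Naive and 11.6 in EpiLC, and Zfp143 reached 31.2 and 11.7. Hexim1, which encodes an inhibitor of the elongation factor P-TEFb, had 15.1 (12.3 to 18.4) in Naive and 18.6 (16.4 to 20.9) in EpiLC. The gene of the immunoprecipitated protein, Pcbp1 (chromosome 6, 86524480 to 86526189), had a peak just outside its annotated end in both lists, at 10.8 (8.13 to 14.1) in Naive and 5.18 (4.11 to 6.45) in EpiLC. Its paralogue Pcbp2 had no gene-end peak in either list.

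The highest EpiLC peak lay in Pou2af1 (chromosome 9, 51238022 to 51238391), at 26.8 against 6.59 at the overlapping Naive peak. Bbc3, a pro-apoptotic BH3-only gene, held an EpiLC peak of 16.9 over a Naive peak of 3.61. Among the 5 highest Naive peaks, those at Zfp37 (25.8) and at Snx12, Mkx and Zfp143 overlapped EpiLC peaks, and that in Ubxn2a (23.0) did not.

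Of the EpiLC peaks, 1689 of 3494 overlapped a Naive peak (48.3%, 95% exact binomial interval 46.7 to 50.01), against 0.377% for random placements. Of the Naive peaks, 1657 of 12132 overlapped an EpiLC peak (13.7%, 13.1 to 14.3), against 0.103% at random and a ceiling of 28.8% set by the shorter list. This left 10475 peaks in the Naive list alone and 1805 in the EpiLC list alone. Among the 50 strongest Naive peaks 48.0% were shared (33.7 to 62.6), among the 100 strongest 34.0% (24.8 to 44.2), and among the 100 strongest EpiLC peaks 79.0% (69.7 to 86.5). Sharing of EpiLC peaks did not rise steadily with fold. In 5 equal groups from weakest to strongest it was 58.5%, 51.2%, 41.8%, 40.6% and 49.5%. With the Naive list shortened to 3494 peaks, the share of EpiLC peaks overlapping a Naive peak was 24.8%.

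Summits gathered at gene ends in both lists, with 31.7% (30.8 to 32.5) of Naive and 31.0% (29.5 to 32.6) of EpiLC summits within 1 kb, against 3.16% and 3.06% at random. Shared peaks lay there most often, at 42.8% of shared Naive peaks (40.5 to 45.3). The share was 29.9% (29.0 to 30.8) for peaks in the Naive list alone and 20.0% (18.2 to 21.9) for peaks in the EpiLC list alone. Gene-end peaks marked 4230 protein-coding genes in Naive (19.3%) and 1228 in EpiLC (5.61%). Of these, 895 had one in both lists, 3.77 times the 237 expected of independent lists.

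Genes of naive pluripotency were frequent in the Naive list and genes of primed pluripotency in the EpiLC list. Of 24 naive pluripotency genes, 13 had a gene-end peak in Naive and 1 in EpiLC. The strongest in Naive were Fbxo15 (10.2, 7.62 to 13.4), Spp1 (8.39), Stat3, which transmits the LIF signal (7.39), and Zfp42, also known as Rex1 (5.79). Nanog, a homeobox factor of the naive network (chromosome 6, 122707489 to 122714633), had a Naive peak of 4.84 (3.38 to 6.74) at its gene end and Klf4 one of 2.79 (1.76 to 4.24), with no gene-end peak at either in EpiLC. Of 30 primed pluripotency genes, 11 had a gene-end peak in EpiLC and 1 in Naive. Sall2 (7.02, 5.45 to 8.90), Pou3f1 (4.37, 3.13 to 5.96), Etv4 (4.03, 3.01 to 5.31) and Fgf5, a marker of the primed epiblast (chromosome 5, 98254184 to 98277033; fold 3.44, 2.43 to 4.72), had gene-end peaks in EpiLC and none in Naive, while Spry4 had one in both lists (4.55 in Naive, 4.76 in EpiLC). Otx2, another primed factor, had no gene-end peak in either list. Within 50 kb of it lay 5 Naive-only peaks and 1 EpiLC-only peak.

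Naive genes were over-represented among Naive gene-end peaks (odds ratio 4.95, adjusted p = 4.86e-04, Fisher's exact test) and not among EpiLC ones (odds ratio 0.731, adjusted p = 1.00, Fisher's exact test). Primed genes were over-represented in EpiLC (odds ratio 9.82, adjusted p = 1.25e-06, Fisher's exact test). Their scarcity in Naive (odds ratio 0.144, adjusted p = 0.0476, Fisher's exact test) did not hold within 3000 bp of gene ends, where 23.3% of them had a Naive peak (adjusted p = 1.00, Fisher's exact test). Among genes with a gene-end peak in 1 list only, all 10 primed genes were in the EpiLC list, against 8.83% of other genes (adjusted p = 8.73e-10, Fisher's exact test). Within 3000 bp, 5 primed genes were in Naive alone and 10 in EpiLC alone, against 9.98% of other genes in EpiLC alone (adjusted p = 5.27e-06, Fisher's exact test). Within 1 kb, all 12 naive genes in 1 list only were in the Naive list, beside a 9.11% EpiLC share of other genes (adjusted p = 0.944, Fisher's exact test). With other genes mostly in Naive too, the test could not have called any split of 12 genes towards Naive. At a fold of at least 5, where 434 EpiLC peaks were left, the calls for naive genes in Naive (adjusted p = 0.339, Fisher's exact test) and for primed genes in EpiLC (adjusted p = 0.540, Fisher's exact test) were lost, as was the split of primed genes, with 1 gene left (adjusted p = 0.762, Fisher's exact test).

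Peaks farther from these genes were also counted, each once. Within 50 kb of the 24 naive genes lay 105 Naive-only peaks, 3.69 times the number around random genes of matched length, with at least 1 at each of the 24 genes. None of 10000 random lists held as many, and without Tbx3, the gene with most, the ratio was 3.54. The 30 primed genes had 25 EpiLC-only peaks, 4.55 times the random number, with 1 of 10000 random lists as high, and 3.80 times without Fgf5, which had 5. Naive-only peaks around primed genes numbered 39, 1.07 times the random number, and EpiLC-only peaks around naive genes 4, 0.973 times. An excess of EpiLC-only peaks was not particular to primed genes. The ratio was 4.71 for trophectoderm genes (2.08 without Tfap2a) and 3.84 for neuroectoderm genes (2.88 without Dlx5).

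**Figure D1:**
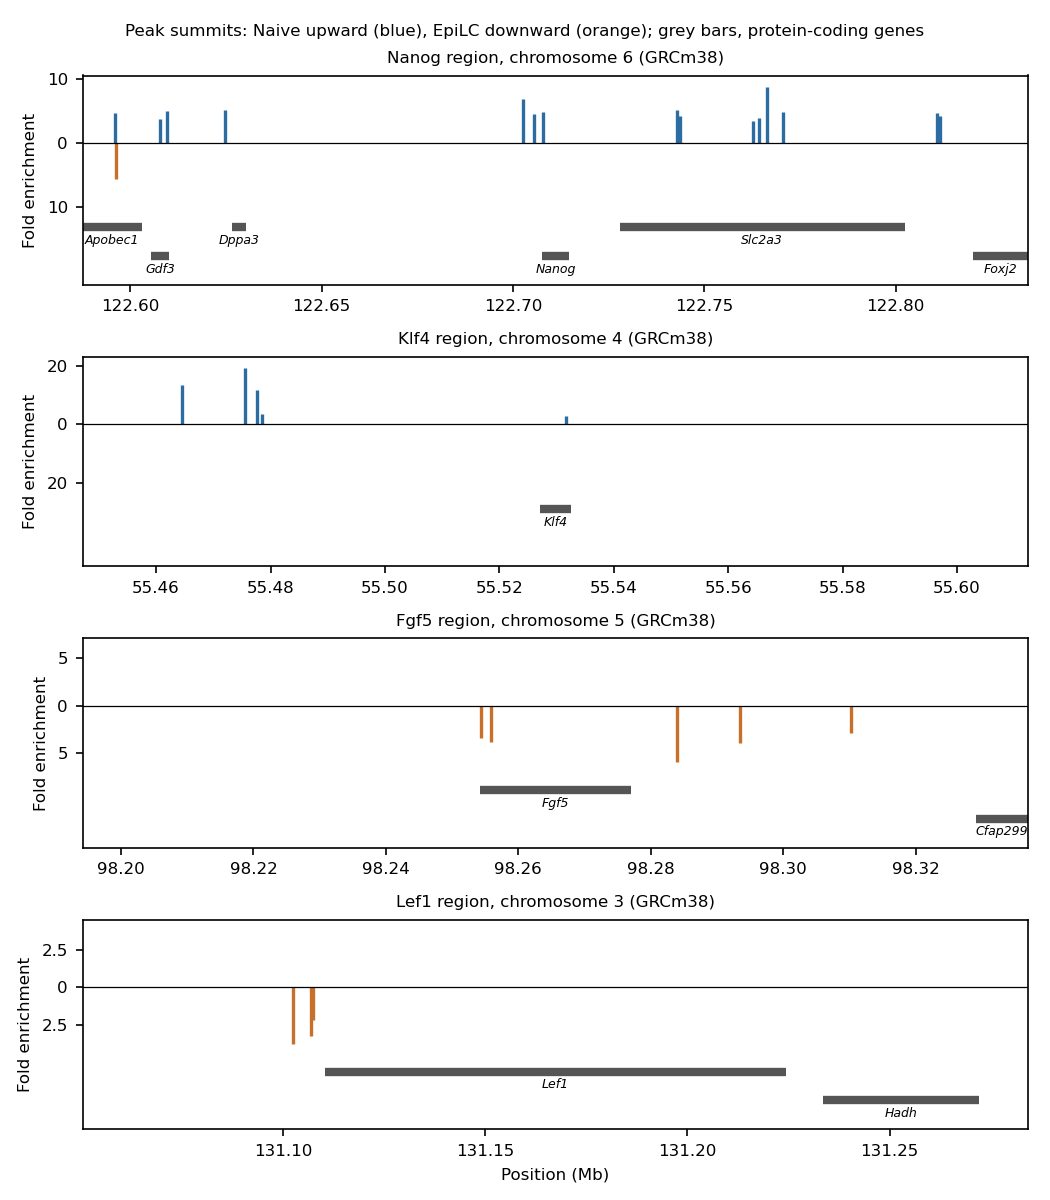
Peak summits (vertical lines, height is the authors' fold enrichment) along GRCm38 positions in Mb around Nanog, Klf4, Fgf5 and Lef1, regions chosen after their values were seen, with Naive upward in blue, EpiLC downward in orange and protein-coding genes as grey bars. The Nanog window held 15 Naive peaks and 1 EpiLC peak and the Klf4 window 5 and 0, while the Fgf5 window held 0 and 5 and the Lef1 window 0 and 3.

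Pluripotency genes shared by both states were found in both lists. Of 17 core genes, 7 had a gene-end peak in Naive (odds ratio 2.93, adjusted p = 0.0659, Fisher's exact test) and 5 in EpiLC (odds ratio 7.03, adjusted p = 0.00559, Fisher's exact test). The EpiLC call was lost at a −log10 q of at least 5 (adjusted p = 0.315, Fisher's exact test), and the Naive list passed within 3000 bp of gene ends (adjusted p = 0.00564, Fisher's exact test). Pou5f1, which encodes Oct4, had a fold of 5.12 (3.53 to 7.20) in Naive and 3.42 (2.55 to 4.48) in EpiLC. L1td1 had 4.85 and 2.25. Utf1 had 4.83 and 2.21 at peaks that did not overlap, and Rif1 had a gene-end peak of 15.99 (12.7 to 19.9) in Naive with none in EpiLC.

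Genes of serine, glycine and one-carbon metabolism had more gene-end peaks in the longer Naive list than in the EpiLC list, as genes at large did. Of the 28 genes, 13 had a gene-end peak in Naive and 1 in EpiLC. Among them were Mtrr, whose peak also lay at Fastkd3 (5.78), Tyms, the thymidylate synthase gene (5.39), and Gcsh of the glycine cleavage system (4.75). Psat1 and Shmt2, enzymes of serine and glycine synthesis, had Naive peaks of 3.80 (2.33 to 5.88) and 3.75 (2.41 to 5.60) and none in EpiLC. Psph, at a peak also assigned to Cct6a, was the member with peaks in both lists, at 4.996 and 2.35, and Phgdh had no gene-end peak in either. The list was over-represented in Naive (odds ratio 3.63, adjusted p = 0.00316, Fisher's exact test) but not with the Naive list shortened to 3494 peaks (adjusted p = 0.885, Fisher's exact test) or at a fold of at least 5 (adjusted p = 1.00, Fisher's exact test). Its split between the peak lists was 12 genes in Naive alone and 0 in EpiLC alone (adjusted p = 0.944, Fisher's exact test). No split of 12 genes lies further towards Naive, so the test could not have called one in that direction. With 3494 Naive peaks, 2 of these genes were in Naive alone and 1 in EpiLC alone (adjusted p = 0.945, Fisher's exact test). Of other genes, 51.3% were then in EpiLC alone.

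The aminoacyl-tRNA synthetase list and genes of mTORC1 signalling, which senses amino acids, were over-represented in both lists. This was not particular to amino acid genes. Odds ratios in Naive were 18.0 for ribosomal proteins, 8.39 for translation factors and 7.42 for the respiratory chain. Here and for the serine list, the comparison was with all other protein-coding genes, whether expressed or not. The synthetase list holds genes that charge tRNAs with amino acids and some genes of proteins that form a complex with them. Of its 23 genes, 16 had a gene-end peak in Naive (odds ratio 9.57, adjusted p = 9.73e-07, Fisher's exact test) and 5 in EpiLC (odds ratio 4.69, adjusted p = 0.0207, Fisher's exact test). Aimp1, a gene of such a complex protein and not of a synthetase, had 10.2 in Naive and 4.15 in EpiLC, at a peak shared with Tbck. The synthetase gene Dars had 7.10 and 2.79. Of 38 mTORC1 genes, 22 had one in Naive (odds ratio 5.76, adjusted p = 7.75e-07, Fisher's exact test) and 6 in EpiLC (odds ratio 3.16, adjusted p = 0.0451, Fisher's exact test). Flcn, the folliculin gene, had 10.7 (8.20 to 13.8) and 3.50 (2.74 to 4.42), Tsc1 had 8.19 and 5.31, and Mtor had 5.45 and 2.70. At a −log10 q of at least 5, both EpiLC calls were lost (adjusted p = 0.0561 for the synthetases and 0.410 for mTORC1, Fisher's exact test). The mTORC1 call in Naive was lost with 3494 Naive peaks (adjusted p = 0.280, Fisher's exact test) and at a fold of at least 5 (adjusted p = 0.220, Fisher's exact test).

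Other amino acid lists did not pass the threshold in either peak list. Gene-end peaks in Naive and EpiLC were found at 11 and 1 of 31 genes of branched-chain, lysine, tryptophan and tyrosine degradation, with Naive the nearer to the threshold (odds ratio 2.30, adjusted p = 0.0732, Fisher's exact test). The counts were 8 and 1 of 28 genes of glutamate, proline, arginine and aspartate metabolism, 6 and 3 of 22 of methionine and polyamine metabolism and 6 and 3 of 38 amino acid transporters. Slc3a2, the heavy chain of several amino acid transporters, had 7.07 in Naive and 3.05 in EpiLC. The integrated stress response, which answers amino acid shortage, had 8 and 4 of 21 genes (odds ratio 2.57 in Naive, adjusted p = 0.0900, and 3.97 in EpiLC, adjusted p = 0.0595, Fisher's exact test), and both passed within 500 bp of gene ends (adjusted p = 0.0374 and 0.0302, Fisher's exact test). Its transcription factor gene Atf4 had 8.24 (6.12 to 10.9) in Naive and 3.53 (2.70 to 4.53) in EpiLC. Iron handling, in which Pcbp1 acts as an iron chaperone, had 10 and 4 of 26 genes (odds ratio 2.61 in Naive, adjusted p = 0.0501, Fisher's exact test), Pcbp1 itself among them, and passed in Naive with 3494 Naive peaks (adjusted p = 0.0330, Fisher's exact test).

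Ribosomal protein, histone, splicing, translation factor and respiratory chain genes were over-represented in both lists. Of 84 ribosomal protein genes, 68 had a gene-end peak in Naive (odds ratio 18.0, adjusted p = 7.34e-33, Fisher's exact test) and 56 in EpiLC (odds ratio 35.2, adjusted p = 2.30e-48, Fisher's exact test). Rps27a, at a peak shared with Clhc1, had 11.2 and 3.16, and Rps26 had 8.64 and 3.48. Replication-dependent histones had 28 and 17 of 34 genes (odds ratios 19.6 and 17.0, adjusted p = 3.26e-14 and 3.39e-12, Fisher's exact test). Several of these histone genes had the same fold and interval as another in both lists, as genes at a common peak would. The test counts each gene as independent, so its p-values for the histones are likely too small. Poly-C-binding proteins and splicing factors had 31 and 17 of 48 (odds ratios 7.66 and 9.34, adjusted p = 5.69e-11 and 2.27e-09, Fisher's exact test). Translation factors had 24 and 12 of 36 (odds ratios 8.39 and 8.48, adjusted p = 3.95e-09 and 1.25e-06, Fisher's exact test), with Eif4a2 at 10.3 and 4.76. The respiratory chain had 51 and 14 of 80 (odds ratios 7.42 and 3.60, adjusted p = 4.04e-17 and 4.59e-04, Fisher's exact test), with Atp5o at 11.2 and 2.99. At a fold of at least 5, where few EpiLC peaks were left, 0% of the ribosomal protein, translation factor, respiratory chain and histone genes had a gene-end peak in EpiLC. The call for splicing factors in EpiLC was lost too (2.08%, adjusted p = 0.658, Fisher's exact test). Glycolysis, with 7 and 3 of 23 genes, did not pass in either list within 1 kb but passed in both within 3000 bp (adjusted p = 0.0127 and 0.0141, Fisher's exact test).

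**Figure D2:**
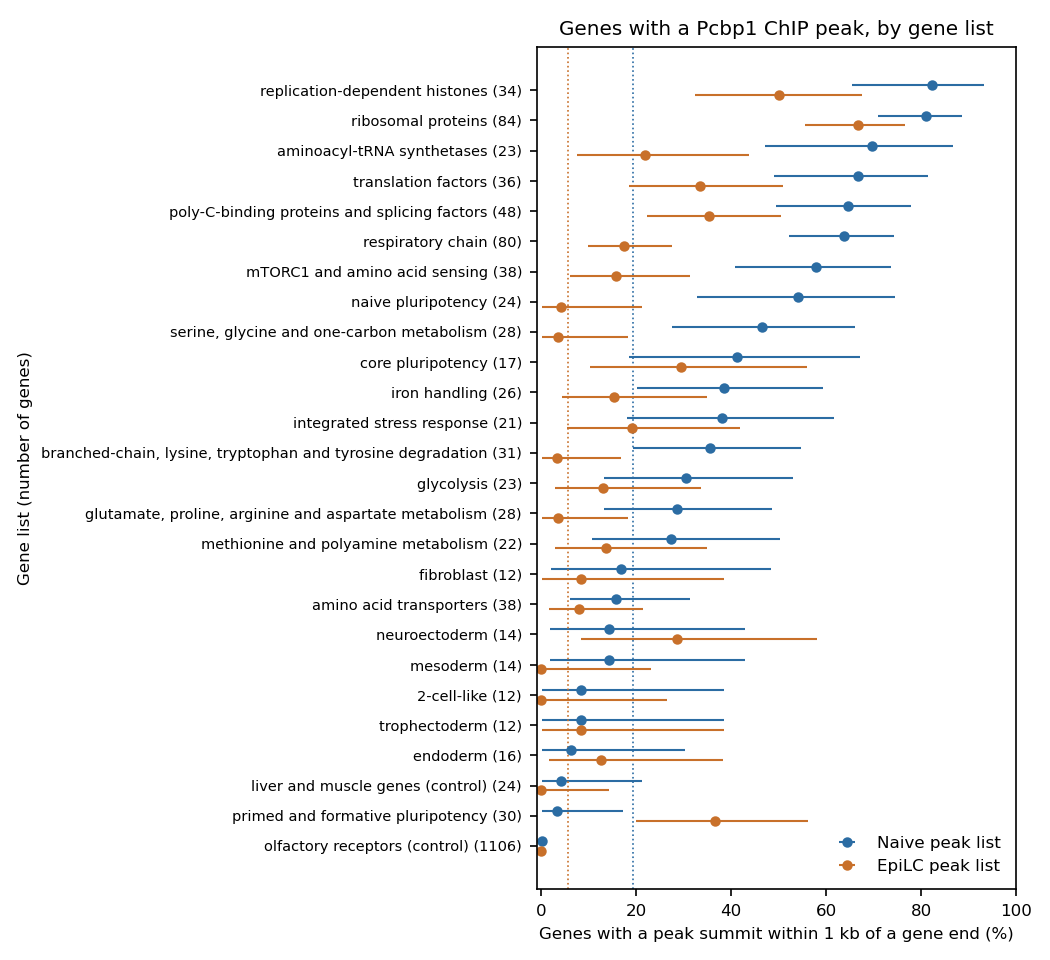
Percent of the genes of each list (number of genes in parentheses) with a peak summit within 1 kb of a gene end in the Naive (blue) and EpiLC (orange) peak lists, with 95% exact binomial intervals as bars and the level of other genes as dotted lines. Ribosomal protein genes stood at 81.0% and 66.7%, naive pluripotency genes at 54.2% and 4.17%, and primed pluripotency genes at 3.33% and 36.7%.

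Neuroectoderm genes were over-represented in EpiLC, with 4 of 14 (odds ratio 6.75, adjusted p = 0.0172, Fisher's exact test), but not at a −log10 q of at least 5 (adjusted p = 0.247, Fisher's exact test). Nes, the nestin gene, had 7.66 in Naive and 5.92 in EpiLC, and Zic1, at a peak shared with Zic4, had 4.15 in EpiLC. Among genes with a gene-end peak in 1 list only, 1 neuroectoderm gene was in Naive and 3 in EpiLC (adjusted p = 0.0360, Fisher's exact test). This call on few genes was lost with 3494 Naive peaks (adjusted p = 0.611), at a −log10 q of at least 5 (0.968) and within 500 bp (0.204) or 3000 bp (0.0503) of gene ends (Fisher's exact test). Endoderm genes had gene-end peaks at 1 of 16 in Naive and 2 of 16 in EpiLC, trophectoderm genes at 1 and 1 of 12, mesoderm genes at 2 and 0 of 14, fibroblast genes at 2 and 1 of 12, and 2-cell-like genes at 1 and 0 of 12, none of which passed the threshold. Of 1106 olfactory receptor genes, silent in these cells as a rule, 1 had a gene-end peak in Naive and 0 in EpiLC (odds ratio 0.00354 in Naive, adjusted p = 1.38e-102, Fisher's exact test). Liver and muscle genes had 1 and 0 of 24.

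The strongest gene-end peaks in 1 list belonged to genes of varied function. In Naive alone these were Rif1, Ifitm2 (13.4), Ccr10 with Plekhh3 (11.04), Med11, Fam189a1, Smc3 (each 10.8), Sp5 (10.4) and Fbxo15. In EpiLC alone they included Mbd2 (14.6), Prdm11 (10.4), Foxe3 (7.83), Zfp629 (7.20), Glra1 (7.14), Sall2 and Kcnn2 (6.98). The Mbd2 peak overlapped a Naive peak of 10.4 with its summit beyond 1 kb, and the Ccr10 peak overlapped an EpiLC peak. Across all genes, this held for 12 of the 333 in EpiLC alone and 10 of the 3335 in Naive alone.

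At the 1657 shared Naive peaks the authors' fold was lower in EpiLC, with a median log2 ratio of EpiLC to Naive of -0.55 (95% bootstrap interval -0.59 to -0.52) and 251 peaks higher in EpiLC. Spearman's rho across these peaks, which are not independent replicates, was 0.385 (0.336 to 0.430). Summit pileup over the genome-wide background differed less, with a median log2 ratio of -0.13 and a rho of 0.706. The local background used for the fold was higher in EpiLC, with a median log2 ratio of 0.60. The fold was made separately in each list, so this ratio is not a measure of a change in binding.

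**Figure D3:**
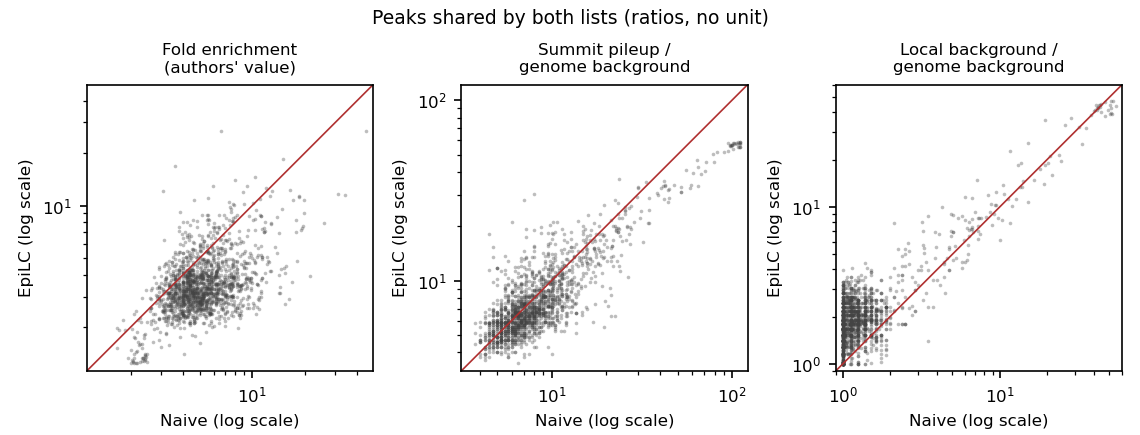
Fold enrichment, summit pileup over the genome-wide background and local over genome-wide background at the 1657 shared peaks, Naive on the horizontal and EpiLC on the vertical log axis (ratios without unit), with 1 point per peak and the line of equal values in red. Folds lay mostly below the line, pileups along it, and local backgrounds mostly above it, with medians of 1.14 in Naive and 1.92 in EpiLC.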

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

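The tests in this part, apart from the over-representation of gene lists, were chosen after the results they bear on had been seen, and the bounds that decide them were set then too. Peaks outside the main chromosomes had no part in the comparisons of genes: 5 Naive peaks lay on the mitochondrial chromosome, and 36 Naive and 38 EpiLC peaks lay on unplaced or unlocalised contigs. Of the contig peaks, 23 Naive and 29 EpiLC peaks lay on JH584304, where the median local background was 43.6 and 42.4 times the genome-wide one.

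The EpiLC list was shorter than the Naive list by a factor of 3.47. Lower depth in EpiLC would need a lower genome-wide background, and that of EpiLC was 1.86 times the Naive one, with shortest peaks of 219 and 222 bp. A uniformly weaker enrichment would lose the weakest peaks first, and it stays open, since the share overlapping an EpiLC peak was 8.66% to 13.8% in the lower 4 of 5 equal groups of Naive peaks ranked by fold, 23.1% in the highest group, 34.0% among the 100 strongest and 48.0% (33.7 to 62.6) among the 50 strongest. The higher local background of EpiLC may have hidden peaks: raised by the 1.52 times seen at shared peaks it would leave 96.2% of Naive-only peaks above the EpiLC threshold, and raised 3 times 31.0%, but the EpiLC background at those sites was not measured here. With 1 ChIP library per condition, a difference between cultures, days or libraries cannot be told apart from the change of cell state, which stays open too.

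Naive pluripotency genes were over-represented at Naive gene-end peaks (13 of 24) and primed ones at EpiLC gene-end peaks (11 of 30). A general loss of peaks in EpiLC would split primed genes like other genes, and they split otherwise (adjusted p = 8.73e-10, Fisher's exact test). The same test could not decide for naive genes (12 in Naive alone and 0 in EpiLC alone, adjusted p = 0.944, Fisher's exact test). Their split was already the furthest possible towards Naive, where most other genes lay too. With equal numbers of peaks, 51.4% of other genes in 1 list were in EpiLC alone. Of naive genes, 5 were then in Naive alone and 1 in EpiLC alone, which was not called (adjusted p = 0.423, Fisher's exact test). A further test, added for naive genes after that, asked whether the Naive peaks within 50 kb of them were shared at the common rate: 3 of 108 (2.78%, exact binomial interval 0.577 to 7.90) overlapped an EpiLC peak, against 13.6% of other Naive peaks matched on gene-end position and fold (95% of draws between 7.41% and 20.4%). Neighbouring peaks are not independent, and with the naive genes drawn again in place of peaks, the 95% bootstrap interval of this share was 0% to 6.06%. Enrichment of open or active chromatin whatever the antibody is a candidate explanation, since ribosomal protein genes, active in both states, had gene-end peaks at 81.0% in Naive, and without an antibody control or cells lacking Pcbp1 it stays open beside binding by Pcbp1.

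EpiLC-only peaks crowded into 10 windows of 1 Mb with at least 10 such peaks each, where the highest count was 22 and random placement reached 9. On chromosome 14, between 3000000 and 8000000, 91 lay among predicted genes, most of them with Gm symbols, and 17 lay in the Snrpn and Ube3a window of chromosome 7, which holds 206 small nucleolar RNA genes. Reads shared between near-identical copies, or extra copies of a region, may account for this, since the median local background in the windows was 1.71 times that at other EpiLC-only peaks (2.30 against 1.34). The windows on chromosome X at 94000000 (1.23) and chromosome 15 at 102000000 (1.51) showed little of it. Naive peaks were fewer than EpiLC-only peaks in most windows. They numbered 6 against 22 at 7000000 and 1 against 20 at 3000000 on chromosome 14, and 3 against 17 in the Snrpn window. The exceptions were chromosome 8 at 20000000 (26 against 16) and chromosome 15 at 102000000 (15 against 10). Why copies in the same cell line would give fewer Naive peaks was not tested. No biological explanation was tested.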

How the results depend on the processing

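No paired analysis was possible because each condition had 1 ChIP library. The GC-matched random lists, the search for C-rich sequence and the window at first transcript starts were not run. The crowded-window, length-matched and pileup alternatives, those for the split of gene lists and for the folds of single genes, for shared peaks the fold and equal-number ones, and the limit to chromosomes 1 to 19 and X for all but peak numbers and overlap shares, were chosen after seeing the data. Peak numbers stayed within 1.5 times with nearby peaks merged, without crowded windows, at a −log10 q of at least 5 or on chromosomes 1 to 19 and X. The share of EpiLC peaks overlapping a Naive peak was 44.7% at a −log10 q of at least 5, 40.6% at a fold of at least 5, 24.8% with equal numbers of peaks, 33.1% with 50% of both peaks covered, 33.9% with summits within 100 bp and 50.3% without crowded windows. The share of Naive peaks overlapping an EpiLC peak was 4.42% at a fold of at least 5, 23.7% with equal numbers, 9.54% with 50% covered and 9.75% by summits. At a fold of at least 5, 3978 Naive and 434 EpiLC peaks were left, with 1494 and 148 genes, and equal numbers left 1193 Naive genes. The gene-end share of Naive peaks was 30.7% at a fold of at least 5, 27.7% with equal numbers, 26.3% within 500 bp and 40.1% within 3000 bp, and that of EpiLC peaks 23.8% and 40.3% in these windows. The median log2 ratio at shared peaks was -0.14 at a fold of at least 5, -0.83 with equal numbers, -0.48 with 50% covered and -0.13 for pileups, and rho was 0.335 at a −log10 q of at least 5, 0.320 at a fold of at least 5, 0.451 with 50% covered and 0.706 for pileups. Lists over-represented in EpiLC fell from 10 to 6 at a −log10 q of at least 5 and to 0 at a fold of at least 5. There, 0% of core pluripotency, aminoacyl-tRNA synthetase, ribosomal protein, translation factor, respiratory chain and histone genes had an EpiLC peak, against more than other genes in the full list. With 148 of 21887 genes left in EpiLC, 0% in lists of these sizes does not show a reversal. The under-represented lists in Naive fell from 2 to 1 at a −log10 q of at least 5, at a fold of at least 5, with equal numbers, within 500 bp and 3000 bp and with length-matched lists. Under these filters and windows the list lost was that of primed genes. The lists that split unlike other genes fell from 2 to 1 at a −log10 q of at least 5 and within 500 bp and 3000 bp, and to 0 at a fold of at least 5. With equal numbers of peaks there were again 2, but neuroectoderm was lost (adjusted p = 0.611, Fisher's exact test) and ribosomal proteins passed, with 88.0% of their genes in 1 list found in EpiLC alone against 50.6% of other genes (adjusted p = 0.00339, Fisher's exact test). In the full lists these shares were 16.7% and 9.04%. Fewer peaks enter under the stricter filters; otherwise the cause was not tested. Of 22 calls on gene lists, 8 held under all 6 alternatives of filter, chromosomes and window and 14 were lost under at least 1, and 6 others passed under at least 1. The Naive fold at Pou5f1 was 8.82 within 3000 bp, where a stronger peak was taken. The lowest summit pileup was 23 in EpiLC and 14 in Naive, beside genome-wide backgrounds of 7.43 and 4.004.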

Other observations

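The tests in this part were chosen after the results were seen. Genes for RNAs that code for no protein held more gene-end peaks than random placement gave. This was not particular to them, since 31.7% of Naive and 31.0% of EpiLC summits lay at the ends of protein-coding genes against 3.16% and 3.06% at random. Long non-coding RNA genes had 817 in Naive against 235 at random and 282 in EpiLC against 69.0, and microRNA genes 67 against 11.9 and 22 against 3.45. Of 1340 small nucleolar RNA genes, 73 had a peak within 1 kb in Naive against 13.0 at random, and 71 in EpiLC against 3.75. Of 1004 small nuclear RNA genes, which serve splicing, 51 had one in Naive against 10.9 and 42 in EpiLC against 2.25. Of 63 ribosomal RNA genes, 13 had one in Naive and 8 in EpiLC, against 0.550 and 0.250. Transfer RNA genes had 22 of 408 in Naive, where random placements averaged 3.75 and reached 16, and 5 in EpiLC, where they averaged 0.9. Pseudogenes had fewer than at random, 93 against 136 in Naive and 18 against 38.3 in EpiLC. Many of these genes lie in clusters or occur in near-identical copies, and random placement took 20 draws without regard to either.

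Within 50 kb of the 34 replication-dependent histone genes lay 32 shared peaks, 4.04 times the number around random genes of matched length, with 21 of 10000 random lists as high. Naive-only peaks there numbered 26, 1.46 times the random number with 1305 lists as high, and EpiLC-only peaks 4, 0.9005 times with 5219 as high. The genes lie in clusters, which the random lists do not.

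The strongest peaks away from gene ends in Naive alone were in or near Ubxn2a, Fblim1 (19.9), Zbtb44 (19.8) and Jam2 (19.4). Of the 10 strongest, 2 had a naive pluripotency gene as the nearest gene, which was not tested against chance. A peak of 19.2 (15.6 to 23.4) lay 51563 bp from Klf4 on chromosome 4 (55475202 to 55476190), beyond the 50 kb used for the counts around genes, and one of 17.8 (14.3 to 21.9) lay 13846 bp from Zfp42 on chromosome 8. Strong ones in EpiLC alone included a peak in Cstad (10.98) and a peak near Spef1l (9.35). The genes named here were chosen after their values were seen, Klf4 and Zfp42 for the list they belong to.

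Trophectoderm genes had 10 EpiLC-only peaks within 50 kb of their 12 genes, 4.71 times the random number, of which 6 lay at Tfap2a, and 2.08 times without it. Neuroectoderm genes had 10 at 14 genes, 3.84 times the random number and 2.88 times without Dlx5. Naive-only peaks numbered 16 at the former, 1.12 times the random number, and 7 at the latter, 0.421 times.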
